A study of Mus musculus with 8 samples.

How the data were processed

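Whole-genome bisulfite sequencing libraries from muscle stem cells of 4 young and 4 old mice, 1 animal per library, were grouped by the age in the labels. Per the labels' protocols, 150 ng of DNA went into each library with 14 PCR cycles, and reads were paired-end of 101 bp. Per the submitters' processing notes, Trim Galore, Bismark and edgeR were used with builds mm10 and GRCm38; versions and the role of each tool are not given in the sources used here. The deposited values come as 1 table for the series. Its levels are given per the file headers as mu for each age, a fraction from 0 to 1 that the authors computed per group and that is equal over neighbouring positions in many places, so it was smoothed along the chromosome. The table also gives, per the file headers, a dispersion (phi) for each age, a number between 0 and 1 from the authors whose definition is not given in the sources used here. The authors' p-value of old against young and its FDR, also a p-value by unit, are deposited for each position; the FDR column equals a Benjamini-Hochberg adjustment of the p column over all rows to within 0.0856%. The tool that smoothed and tested is not given in the sources used here.

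Because values per library and read counts are not in this table, the tests planned before the data were examined (exact permutation tests over 8 libraries, edgeR and moderated logistic models on read counts, other splits of the samples) were not run, and coverage minimums could not be set. Depth per position is unknown. Levels were averaged in percent over positions with equal weight, on chromosomes 1 to 19 and X unless said otherwise. Smoothing pools neighbours, so levels and differences of adjacent positions are not independent, narrow differences are flattened, and counts of positions overstate the number of separate events. The spread over chromosomes is given as a description and is not a replicate error, since all chromosomes share the same animals.

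A feature (1-kb tile, gene end, gene span) was tested by 2 times the median of the authors' p over its positions, which bounds the feature's p under any dependence between positions, with Benjamini-Hochberg adjustment over features of at least 10 positions and calls at 0.05. The authors' deposited p-values enter this test as they are, so any error in them carries over. The procedure was checked on simulated data on the positions of chromosome 19 with 200 of 33920 tiles changed by 30 points. At a standard error of 5 points it recovered 99.5% with 1 false call. With isolated small p added it recovered 99.5% with 0 false calls. At 10 points it recovered 4%. Young levels were simulated as equal everywhere and p as uniform in unchanged tiles, whereas the deposited p-values had a median of 0.687. The standard error of the deposited levels is not known, so these rates do not give the power in these data.

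Gene spans came from a RefSeq gene table of GRCm38.p6, the same build family as mm10, with 21627 protein-coding genes on the chromosomes used. It gives no strand, exons or sequence, so promoters, CpG islands, exons, introns and repeats were not analysed here, and windows of 1000 bp on each side of both ends of each gene stood in for promoters. The end with the lower mean over both ages is called the less methylated end. Levels fell from 68.6% at 5000 to 10000 bp from a gene end to 16.9% within 200 bp, in young cells, so the coordinates of both tables match. Positions are printed as the deposited table gives them. Of 715 genes in 21 lists fixed before the data were examined, 713 were in the gene table. A list's mean difference was compared with 10000 random lists matched on level and number of positions (two-sided share, adjusted over the 21 lists within each of 3 kinds of window: 1000 bp and 2000 bp around the less methylated end, and the span).

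The rule for named genes, fixed before the data were examined, takes for each kind of feature those past the threshold with at least 10 points of difference and otherwise the 5 with the smallest p in each direction, said not to meet it, and 11 genes always: Pax7, Myod1, Myog, Myf5, Spry1, Vcam1, Cdkn2a, Dnmt3a, Hes1, Hey1 and Heyl. Its condition on separate values per animal could not be applied. Values of some genes are not reported here. Members of lists named as examples beyond this rule were chosen after their values were seen. Also chosen after seeing the data were the test by the median, the tile minimum of 10 positions (6, 20 and 40 were also looked at), runs of positions (p under 0.01 with at least 10 positions; p under 0.001 with at least 6, and a smaller p with fewer positions, were also looked at), gene end windows, the comparison of both strands and the matched random lists. Further alternatives were 5000-bp tiles, autosomes only, windows of 2000 bp, nearest-neighbour matching and leaving out positions at the most common dispersion value of either group (0.0438 in young, 0.0434 in old). Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.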

Results

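DNA methylation was measured by whole-genome bisulfite sequencing, which reads unmethylated cytosines as thymines, in quiescent muscle stem cells of male C57BL/6 mice. The cells, which rest beside the muscle fibre until injury calls on them, were sorted from limb muscle as negative for CD45, CD31 and Sca1 and positive for VCAM. Libraries were made from 4 young mice (4 months) and 4 old mice (22 months), 1 animal per library, and the question is how methylation in these cells differs with age. The deposited table gives, for each of 33108039 CpG cytosine positions, 1 smoothed methylation level and 1 dispersion per age group with the authors' own p-value and FDR. It holds no value per animal and no read count, so levels below are the authors' group means, stand without an SD, and have an unknown depth per position; the labels state 115000000 to 200000000 reads per library.

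Old muscle stem cells were slightly more methylated than young ones across the genome, at 64.6% against 64.1% over 32984740 positions of chromosomes 1 to 19 and X, a difference of 0.473 percentage points. The direction was shared by all 20 chromosomes, from 0.409 points on chromosome 11 to 0.584 points on chromosome X (SD over chromosomes 0.0443 points). Sequence that was nearly unmethylated went the other way: positions with a mean level under 20%, the state of most CpG-rich gene starts, stood at 6.15% in old against 6.28% in young cells and were lower in old on 20 of 20 chromosomes, by -0.0807 to -0.262 points. Mitochondrial positions were also lower in old, by -0.104 points. Less complete bisulfite conversion in the young libraries therefore cannot be told apart from a change with age at these low positions. Positions between 60% and 80% showed the widest gap, at 71.9% in old against 71.3% in young cells. Levels per animal are not in the table, so the difference between the ages could not be tested against the spread between animals.

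**Figure D1:**
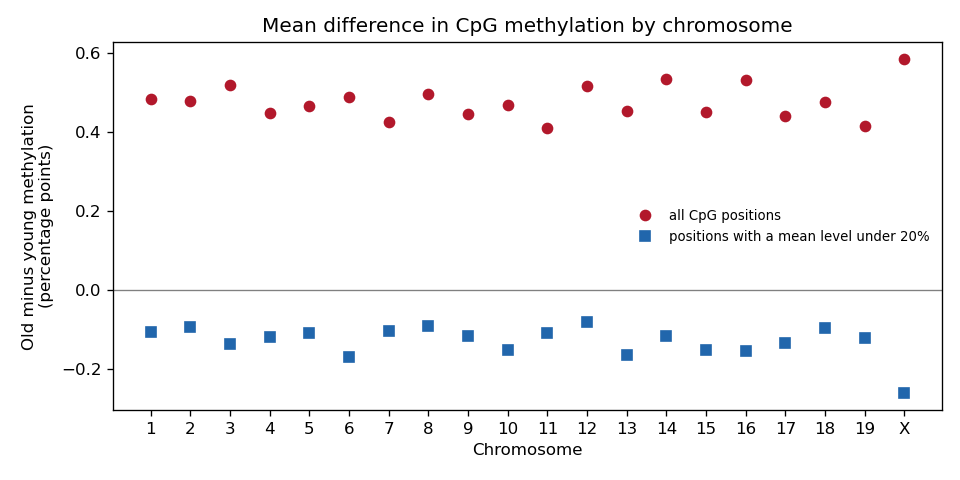
Mean old minus young difference in CpG methylation (percentage points, vertical axis) for each chromosome (horizontal axis), over all positions (circles) and over positions with a mean level under 20% (squares). All 20 circles lie above 0, between 0.409 and 0.584 points, and all 20 squares lie below 0.

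Sequence between genes and gene bodies showed a larger difference than gene ends did. Over 1 kb outside every gene of the table the level was 68.7% in old against 68.2% in young cells, and inside protein-coding genes it was 69.1% against 68.6%. Within 1 kb of an end of a protein-coding gene the levels were 25.9% and 25.8%, a difference of 0.112 points, with 20 of 20 chromosomes higher in old. It becomes -0.361 points once the genome-wide difference is subtracted. The difference varied with level, so this value does not set gene ends apart from other sequence of their level. The gap narrowed as CpGs became denser. In 1-kb tiles with 1 to 4 CpGs old cells were higher by 0.619 points, in tiles with 20 to 39 CpGs by 0.442 points, and in tiles with 60 or more CpGs, which are island-like in density, both ages stood at 6.89% to 6.90% with 12 of 20 chromosomes higher in old. On chromosome Y, outside the main set, old cells stood at 70.9% against 69.99%, and on mitochondrial DNA the levels were 1.08% in old and 1.18% in young cells.

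Single CpG positions passed the authors' test in both directions, with somewhat more of them higher in old cells. On chromosomes 1 to 19 and X, 77990 positions had an FDR under 0.05 in the authors' deposited table, 43411 higher and 34579 lower in old, with median differences of 19 and -19.02 points. Of these calls 91.7% lay at the most common dispersion value of at least 1 age group, and 6467 were left without such positions, 3698 of them higher in old. These are 0.236% of the positions, and 69048 of them differed by at least 10 points. They lay mostly in CpG-poor sequence: 128 per 10000 positions in tiles with 1 to 4 CpGs passed, against 0.189 per 10000 in tiles with 40 to 59 CpGs. The position with the smallest p in the authors' deposited table, at 21972553 on chromosome 13, stood at 56.3% in young and 87.4% in old cells and had the most common dispersion value in both groups. Of called positions differing by at least 2 points, 87.1% had a p smaller than the printed dispersion seems to allow. The share was 42.7% over all positions, and the limit used is described further below. A call itself requires a small p, so the higher share among called positions is partly set by their selection.

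The calls rarely covered both strands of a CpG. Among 14945647 CpGs with both cytosines listed, 94.1% had the same group levels on both strands, yet only 1039 CpGs passed on both strands, 602 higher and 437 lower in old; 2.79% of called positions had a called partner. The partner's p in the authors' deposited table had a median of 0.0986. Lrrc4c and Lsamp, which encode neuronal cell-surface proteins, and Sil1 were among the genes with the most such CpGs within 1 kb of their spans (4 each); those of Lsamp were all higher in old, and those of Sil1 all lower. Of the fixed gene lists, Foxa1 and Pax5 (developmental regulators of endoderm and of B cells) held 2 each, all lower in old, and Rora, a nuclear receptor of the circadian clock, held 2, both higher in old. In all, 306 of 21633 genes held at least 1.

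**Figure D2:**
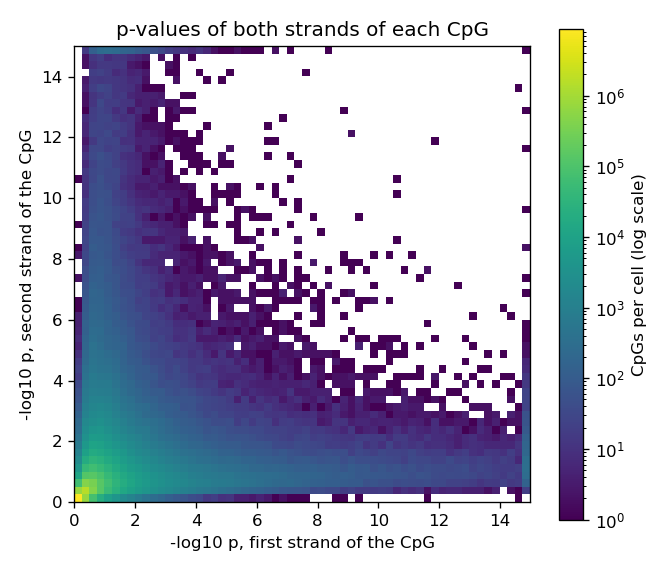
Number of CpGs (colour, log scale) by the authors' p on the first strand (horizontal axis, -log10) and on the second strand (vertical axis, -log10), with values over 15 drawn at 15. CpGs with a very small p on one strand lie along the axes, and 1039 CpGs passed the authors' FDR of 0.05 on both.

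One tile of 1 kb fell in methylation, from 78.0% in young to 43.6% in old cells, at 10786000 to 10786999 on chromosome 6, over 1 Mb from the nearest protein-coding gene, Ndufa4. It was the 1 call among 1231304 tiles with at least 10 positions (16 positions, 2 times the median of the authors' p 9.11e-10, Benjamini-Hochberg adjusted p 0.00112). The drop came from 11 positions within 25 bp, where the level went from 91.7% to 39.8%. Over all tiles 97.9% differed by less than 10 points, 15902 were at least 10 points higher and 10303 at least 10 points lower in old. Before adjustment 1309 tiles had a p under 0.05, 762 higher and 547 lower. With 5000-bp tiles no tile passed.

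The other tiles that the naming rule gave did not meet its threshold (adjusted p 1 each). Higher in old were tiles in Rnf128, a ubiquitin ligase gene on chromosome X (46.5% to 71.1%), and in the interferon-inducible GTPase gene 9930111J21Rik1 (61.8% to 89.0%). Also higher were tiles nearest to Cdh12, at 674 kb (75.2% to 96.5%), to the histone gene H2bc15, at 11.4 kb (33.5% to 56.3%), and to Klf4, at 281 kb (53.6% to 79.3%). Lower in old were tiles in Aff2 on chromosome X (89.2% to 35.3%) and Sil1 (85.8% to 49.6%). Also lower were tiles nearest to Col12a1, at 350 kb (79.2% to 38.2%), and to the growth arrest gene Gadd45a, at 78.6 kb (59.04% to 26.6%). The tiles in Rnf128 and Aff2 each held 11 neighbouring positions with a small p, within 23 bp and 21 bp. All of these had the most common dispersion value in both groups, where p could be too small.

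Runs of neighbouring positions that all leaned the same way picked out short regions, and the regions named here were chosen after their values were seen. A run had at least 10 positions with p under 0.01 in the authors' deposited table, gaps of at most 100 bp and 1 sign. There were 166 such runs, 91 higher and 75 lower in old, with a median length of 165 bp, and 70 lay inside protein-coding genes. Of these runs 115 held no position that passed the FDR of 0.05 in the authors' deposited table. Of the 25 runs with at least 20 positions, 20 were higher in old, and 5 of these 20 lay in 1 stretch at the end of Mid1. Runs are a description, since no p was adjusted for the search, and without positions at the most common dispersion value 60 runs were left, 38 of them higher.

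A pair of neighbouring runs lay upstream of Rasgrf1, an imprinted gene whose paternal allele is methylated in a region ahead of the gene. At 89879600 to 89879924 on chromosome 9, 29.6 kb from Rasgrf1, the level was 44.8% in young and 68.9% in old cells over 61 positions, and at 89878507 to 89878753 it was 44.5% and 63.5%. Zim1, a gene of the imprinted Peg3 region, held a run at 43.0% in young and 66.2% in old cells. A run in the imprinted gene Plagl1, at 13091565 to 13091759 on chromosome 10, went the other way, from 66.6% to 47.7%. Other runs that were higher in old lay in Gm51792 (27.4% to 53.3% over 62 positions), Arhgap21 (35.03% to 66.6%), the integrin gene Itga2 (45.2% to 66.0%), the Hedgehog receptor component Smo (77.4% to 96.2%) and Sost, an inhibitor of Wnt signalling (22.5% to 39.96%). Runs that were lower in old lay in the calcium-dependent kinase gene Camk2b (84.2% to 69.8%), in Atl3 (86.2% to 61.7%), Ttyh2 (61.9% to 37.7%), Thsd7a (35.1% to 11.4%) and Mb21d2 (25.6% to 9.33%). The longest run by positions, at 56098458 to 56099091 on chromosome 1, was outside genes and stood at 69.0% in young and 86.0% in old cells. Positions past the FDR of 0.05 in the authors' deposited table lay in the runs of Gm51792 (11), Arhgap21 (8) and Thsd7a (3) and in this longest run (1); the runs of Rasgrf1, Zim1, Plagl1, Itga2, Smo, Sost, Camk2b, Atl3, Ttyh2 and Mb21d2 held 0.

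The end of Mid1 on chromosome X, a ubiquitin ligase gene that crosses into the pseudoautosomal region in laboratory mice, held 7 of the runs, all higher in old. They lay between 169979067 and 170005539, a stretch of 26.5 kb, and differed by 18.4 to 30.05 points. The first, inside Mid1, stood at 38.1% in young and 57.4% in old cells, and the last, 14.4 kb beyond the gene, at 34.8% and 55.2%. Over all 771 positions of the stretch the levels were 65.2% in young and 74.7% in old cells. Of the 260 positions in these runs, 20 passed the FDR of 0.05 in the authors' deposited table. The remaining 9 runs on chromosome X included 1 that was higher in old.

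**Figure D3:**
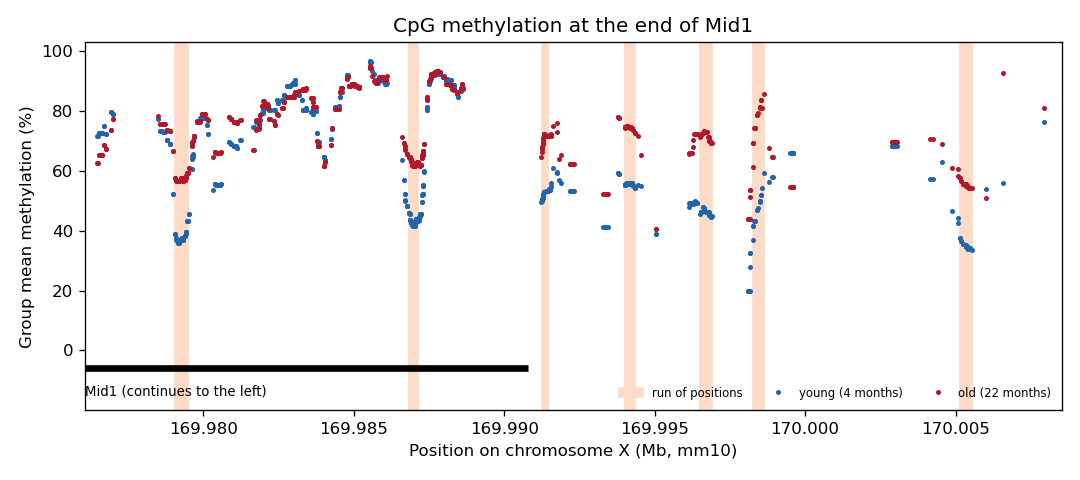
Group mean methylation (percent, vertical axis) of young and old cells at CpG positions around the end of Mid1 on chromosome X (horizontal axis, Mb, mm10), with the span of Mid1 as a black bar and the 7 runs shaded. In each shaded run the old values lie above the young ones, by 18.4 to 30.05 points on average.

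Most genes that define the muscle stem cell and its commitment had nearly the same levels at their less methylated ends in both ages. At the less methylated end of each gene, within 1 kb, Pax7, the master regulator of these cells, stood at 3.88% in young and 4.19% in old cells, Myod1 at 5.66% and 5.51%, Myf5 at 10.9% and 10.5%, and the sort marker Vcam1 at 12.03% and 10.4%. Spry1, an inhibitor of growth factor signalling that keeps these cells quiescent, stood at 2.93% and 3.07%, but held a run near its other end, at 37643575 to 37643794 on chromosome 3, with 18.9% in young and 6.39% in old cells (10 of 19 positions with p under 0.01 in the authors' deposited table, 0 past the FDR); within 1 kb of that end the levels were 16.5% and 11.8%. The Notch targets Hes1 (3.99% and 3.81%), Hey1 (3.06% and 2.90%) and Heyl (3.98% and 3.72%) and the senescence locus Cdkn2a (4.37% and 4.44%) were as low. Myog, which drives differentiation, was at 57.1% in young and 61.1% in old cells, and the less methylated end of the methyltransferase gene Dnmt3a at 65.0% and 63.1%. Over their whole spans Pax7 stood at 29.2% and 29.7%, Cdkn2a at 28.3% and 30.1% and Vcam1 at 49.6% and 47.7%. None of these 11 genes held a CpG called on both strands, but only 306 of 21633 genes did. None had an adjusted p under 1, and neither did any other gene end or span tested. Neither result sets these 11 genes apart.

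No gene end and no gene body passed. Of 38817 end windows of 20442 genes, 0 were called by 2 times the median of the authors' p with Benjamini-Hochberg adjustment (smallest adjusted p 1), and before adjustment 14 had a p under 0.05, 9 higher and 5 lower in old. Those with the smallest p, none of which meets the threshold, were Gm51792 (34.95% to 57.3%), Fnd3c2, Olfr770, Mdfic and Mid1 among the higher ones, and Map3k15 (74.5% to 52.2%), Olfr922, Gm2004, Gm7347 and Dock4 among the lower ones. Mef2c, a transcription factor of muscle differentiation named here after its values were seen, stood at 31.5% in young and 44.8% in old cells at its less methylated end. Of 20485 gene spans 72.0% were higher in old, with means of 57.3% in young and 57.7% in old cells; 0 were called and 2 had an unadjusted p under 0.05. The spans with the smallest p were those of Gm51792 (37.7% to 58.4%), Olfr728, Gm6760, Olfr307 and Serpina7 among the higher ones and of Olfr770 (59.6% to 58.5%), Olfr1032 (81.9% to 66.4%), Vmn2r42, Olfr643 and Olfr1051 among the lower ones. Testing by the median asks that most of a window shifts. It does not use direction: Olfr770 was among the higher ends and the lower spans. Over all positions the authors' p had a median of 0.687, and 2.62% were under 0.05. Windows with few shifted positions thus could not pass, and 0 calls do not show that levels were equal. With simulated shifts of 30 points at every position of 200 tiles of 1 kb it recovered 99.5% at a standard error of 5 points and 4% at 10 points. The standard error of the deposited levels is not known, so the power in these data is not known either. Gene ends and spans were not simulated.

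Transcription factors of other lineages were the one fixed list that stood apart within 1000 bp of its gene ends. Their less methylated ends, many of which are bound by Polycomb proteins in tissues that do not use the gene, stood at 7.31% in old against 7.08% in young cells, a mean difference of 0.224 points over 112 genes, 71 higher and 41 lower. Random lists matched on level and number of positions averaged -0.0720 points with a central 95% from -0.187 to 0.0459. The two-sided share of random lists as far out was 0.0002, the smallest that 10000 lists can give, and 0.0042 after adjustment over the 21 lists. Foxa1, a pioneer factor of endoderm, stood at 11.5% in young and 14.6% in old cells, the forebrain gene Dlx1 at 11.04% and 13.4%, and the cardiac and endodermal factor Gata4 at 22.9% and 25.2%; Prox1, of lymphatic vessels, stood at 9.41% and 8.19%. Over whole gene spans the difference was 0.269 points, above a central 95% that ends at 0.234 (unadjusted share 0.0094), but did not pass after adjustment (0.197). At the ends the difference was 0.136 points without its 5 highest members, a step that lowers any list (adjusted share 0.0924 with nearest matching and untrimmed random lists). These shares compare genes within the group means and not animals, and 0 members of any list passed when adjusted over the list alone.

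Clustered protocadherins, whose promoters are chosen at random by methylation in neurons, stood at 52.0% in old against 50.5% in young cells within 2000 bp of their less methylated ends, with 43 of 58 genes higher (1.52 points, adjusted share 0.0189). Within 1000 bp the difference was 0.727 points and the adjusted share 0.728. Their spans were higher in old in 55 of 58 genes (0.974 points, adjusted share 0.364). The genes sit next to one another, so their values need not be independent, and counts of them are not counts of separate events. The matched random lists drew each gene separately and do not account for this. Of 19923 blocks of 58 neighbouring genes anywhere in the genome, 0.196% had a mean as high within 2000 bp. These blocks were not matched on level and averaged 0.154 points, against 0.371 points for the random lists matched on it, so this share can overstate how far the cluster stands apart.

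Imprinted genes carry methylation on a single parental allele at their control regions. Of 39 genes measured, 20 had a less methylated end between 40% and 60% in both groups, and 15 of these 20 were higher in old. Peg3 stood at 46.2% in young and 50.9% in old cells, Usp29, which shares its start region, at 46.0% and 51.1%, and Kcnq1ot1 at 50.7% and 53.1%; H19 went from 49.0% to 45.4% and Snrpn, on 10 positions, from 53.3% to 44.6%. The list as a whole was inside the range of random lists (0.616 points, adjusted share 0.732).

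The remaining lists lay near their matched random lists, with adjusted shares over 0.05. Muscle stem cell and quiescence genes stood at 8.52% in young and 8.54% in old cells (12 of 29 higher) and myogenic commitment and fibre genes at 43.9% and 44.5% (18 of 32 higher). Notch pathway genes stood at 10.7% and 10.9%, with Rbpj, the transcription factor of the pathway, at 73.1% and 77.5%. Wnt pathway genes stood at 8.06% and 7.98%, FGF receptor and Sprouty genes at 11.6% and 11.5%, and cell cycle inhibitors and senescence genes at 9.29% and 9.09%. TGF-beta and BMP genes stood at 8.82% and 9.15% (unadjusted share 0.0328, adjusted 0.344), and the activin subunit gene Inhba among them at 41.8% and 51.5%. Of these 35 genes 14 were higher and 21 lower in old, with a median of -0.0628 points. Within 2000 bp the list's mean difference was -0.0408 points, with 24 lower. Inflammatory genes stood at 28.0% and 27.4% with 24 of 37 lower in old, among them Il1b (65.9% to 59.6%) and Il6 (19.2% to 16.5%). Of the circadian clock genes 19 of 21 were lower in old, among them Per1 (8.40% to 6.95%), with an adjusted share of 0.631. Germline genes silenced in somatic cells stood at 67.7% and 69.0% (27 of 35 higher), Hox genes at 14.9% and 15.1%, DNA methylation and demethylation enzymes at 19.07% and 19.04%, and extracellular matrix genes at 11.3% and 11.1%.

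Markers of cells that the sort should remove lay inside the central 95% of their matched random lists within 1000 bp of the less methylated ends. Endothelial markers stood at 37.2% in young and 37.7% in old cells, haematopoietic markers at 53.8% and 54.6%, fibro-adipogenic and tenocyte markers at 28.0% and 28.5%, smooth muscle and pericyte markers at 17.1% and 16.6%, and Schwann and neural markers at 24.9% and 24.9%. The adjusted shares ran from 0.631 for smooth muscle and pericyte markers to 0.981 for Schwann and neural markers. Over whole spans endothelial markers stood at 53.97% in old against 53.2% in young cells, with 17 of 20 higher (0.798 points, above a central 95% that ends at 0.753, unadjusted share 0.0346, adjusted 0.363). Ly6a, which encodes the Sca1 antigen gated against, stood at 46.4% in young and 51.7% in old cells.

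**Figure D4:**
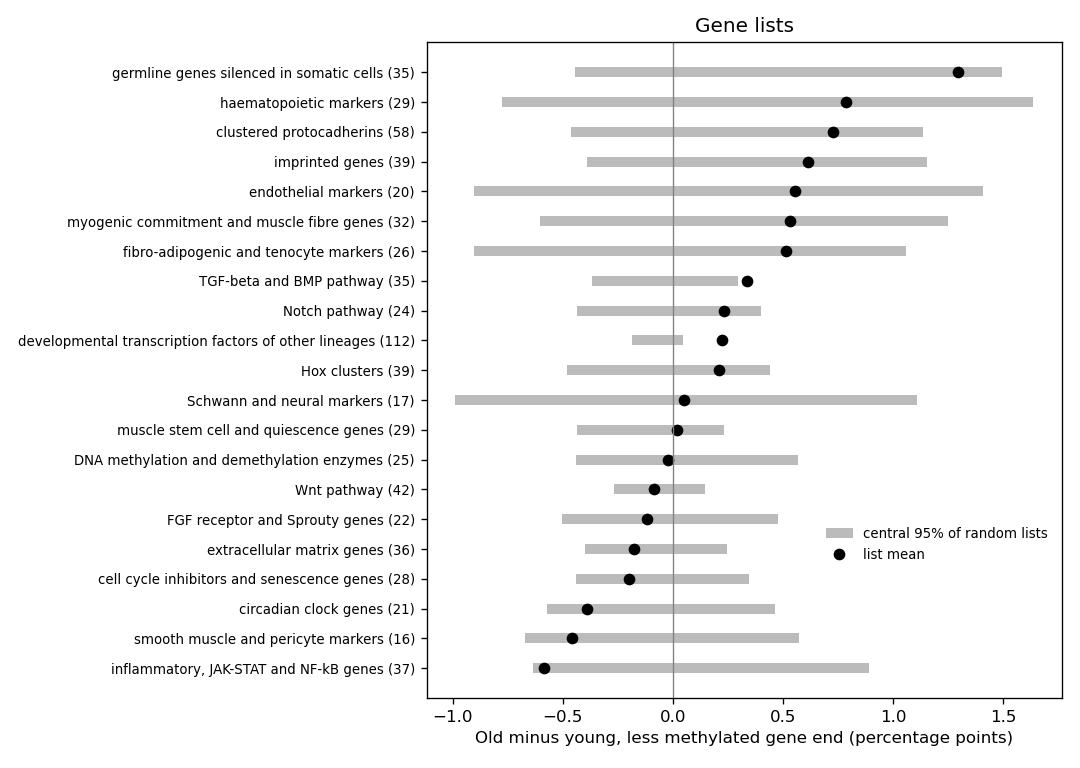
Mean old minus young difference at the less methylated gene end (percentage points, horizontal axis) for each fixed gene list (vertical axis, number of genes measured in parentheses), with the central 95% of 10000 matched random lists as a grey bar. The developmental transcription factors lie at 0.224 points, right of their bar, which ends at 0.0459 points, and the TGF-beta and BMP genes lie right of theirs before adjustment over the lists.

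The authors' dispersion, the nearest the table comes to the spread between animals, was above 0.1 at more positions in old cells. The share was 2.79% in old against 2.33% in young cells, a ratio of 1.20, and was larger in old on 20 of 20 chromosomes. At positions with the most common value in neither group, the dispersion was higher in old at 46.1% and lower at 52.9%. The mean at these same positions was 0.0509 in old and 0.0502 in young cells. The most common value is itself lower in old, at 0.0434 against 0.0438, so the counts do not settle whether dispersion rose in general. Over all positions the mean dispersion was 0.0491 in old and 0.0487 in young cells. The medians, 0.0434 and 0.0438, are the most common values themselves and say little about spread. How the dispersion was estimated is not given in the sources used here, so no test of the spread between animals was made.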

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

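All settings here were chosen after seeing the data except autosomes only, 5000-bp tiles and the subtraction of the genome-wide difference. The genome-wide difference moved by less than the SD over chromosomes (0.0443 points) under each of 4 settings, from 0.461 points without positions at the most common dispersion to 0.497 points over 1-kb tiles. The difference at gene ends was -0.361 points after subtraction of the genome-wide difference. Called positions numbered 51296 at FDR 0.01, 6467 without positions at the most common dispersion and 1039 as CpGs called on both strands. Called tiles numbered 0 at 5000 bp, 3 with at least 6 positions and 0 with at least 20. Gene ends stayed at 0 calls with 2000 bp on each side and gene bodies at 0 with at least 40 positions. Runs numbered 105 at p under 0.001 with at least 6 positions and 60 without positions at the most common dispersion. Lists past an adjusted share of 0.05 numbered 2 with windows of 2000 bp and 0 over gene spans, against 1 in the report. The excess of high dispersion in old cells was 0.599 points without positions at the most common value; the difference in mean dispersion was 0.000475, and that in medians turned to -0.0004. The cause of these changes was not tested.

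No paired analysis was possible because the table holds no values per library. For the same reason leaving out each library, the replicate block, read minimums, reads drawn down to equal depth, the mean over CpGs with a read minimum, edgeR's likelihood ratio test, limma and the quasi-binomial model were not run, nor were windows of 2000 bp upstream, which need the strand, or CpG islands, which need the sequence. Centring list values on the mean of all promoters was replaced by matched random lists, and the spread over promoters was not run.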

Other observations

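Further members of the fixed lists held 1 CpG called on both strands in the authors' deposited table. Higher in old were those in the endothelial gene Emcn, the tendon gene Tnmd, Igfbp7, Socs2 and the smooth muscle kinase gene Mylk; lower were those in the BMP receptor genes Acvr1 and Bmpr1a, in Hormad1, Ms4a1 and Mef2c. Over whole spans Emcn stood at 73.3% in young and 74.1% in old cells, and Tnmd at 66.2% and 69.5%.

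In what follows, the tests of the list with nearest matching, without 5 members and without each chromosome, and those of call rates at a fixed difference, were set out before their results were seen; the other tests were chosen after the pattern was seen.

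The developmental transcription factors, whose ends were higher in old cells by 0.224 points, ran against positions of similar level across the genome. Positions with a mean level under 20%, where 107 of these 112 genes lie, were lower by a mean of -0.130 points (SD over 20 chromosomes 0.0403). These are single positions anywhere and not the genes' own surroundings. The less methylated ends of all genes, at any level, averaged 0.121 points higher in old, with a median of -0.0472. Coarse matching is argued against, since lists drawn from the 20 nearest genes in level and number of positions had a central 95% up to 0.0692 points. Without the 5 members with the largest rises the list stood at 0.136 points, still above its central 95% (two-sided share 0.0044, but 0.0924 adjusted over the lists). Leaving out the largest rises lowers any list, and the random lists were not trimmed alike, so the fall itself shows nothing about these members. Without any 1 chromosome the share was at most 0.001 (adjusted 0.021). Less complete bisulfite conversion in old libraries would raise matched genes alike, and these averaged -0.0501 points. A small age-related gain at such genes may underlie the pattern, as a hypothesis, but with 1 mean per age, chance differences between single animals remain open and untested.

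Only some technical sources of the genome-wide difference of 0.473 points were looked at, and others remain open. Less complete conversion in old libraries would raise unmethylated sequence most, and positions under 20% were lower in old by -0.130 points on average, with mitochondrial positions at -0.104 points. Positions at the most common dispersion value do not carry it, since 0.461 points were left without them. It was shared by 20 of 20 chromosomes, but chance differences between single animals would also be shared by all chromosomes, and without values per animal these cannot be told apart from age.

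Called positions that stand alone on 1 strand made up most calls. At differences of 20 to 30 points, 34.6% of positions with the most common dispersion value in both groups were called against 1.47% with it in neither, a ratio of 23.5, and 73.2% of all calls had it in both groups. A small dispersion by itself does not account for this, since positions with a dispersion under that value in both groups were called 0.0261 times as often. The standard error implied by each p was also set against the least that the animals of each group allow at the printed dispersion. At differences of at least 2 points, 87.1% of called positions fell below this limit, against 42.7% of all positions. The ratio to it was 0.614 at called positions and 1.12 at positions with the most common value in neither group. Calls are chosen by a small p, which lowers the implied standard error. The values at called positions therefore do not show by themselves that p is too small. The limit takes the dispersion as spread between animals, and its definition is not given. The most common value is perhaps one assigned where reads were too few to estimate the dispersion. By the call rates, the p-values of positions at this value could be too small. Whether the CpGs changed with age on both strands cannot be told apart from this for most calls: 2.79% of partners were called, but a partner with few reads can lack power, and reads per position are not in the table.

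Calls were uneven between the strands, at 43145 on the first and 31398 on the second cytosine of a CpG, while the most common dispersion value in both groups was as frequent on both (13.03% and 13.04% of positions).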
